A study of Homo sapiens with 4 samples.

How the data were processed

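Gene expression was measured in MDA-LM2 shDicer cells, a metastatic derivative of the human breast cancer line MDA-MB-231 that carries a hairpin against Dicer, 48 h after transfection with an siRNA against TARBP2 or a control siRNA. Per the labels' protocols, total RNA was treated with DNase on the column, amplified and biotin-labelled, and hybridised to Illumina BeadChips. Each of the 4 arrays is labelled as a separate sample: siTARBP2-1 and siTARBP2-2, which the series' design text describes as independent siRNAs, and siControl-1 and siControl-2. The siRNA sequences are not given in the sources used here. The groups were taken from the transfection labels, 2 arrays each.

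The authors deposited the signal intensity of 47323 probes on each array before normalization, on a linear scale, and beside each intensity a detection p-value, per the file headers. The lowest intensities lay between 35.0 and 37.8 on the 4 arrays, so from the values background had not been subtracted. A second deposited table, the series matrix, holds intensities on a linear scale. Its 4 columns share a lowest value of 33.9 and a highest value of 29951, with medians between 68.4 and 68.5. Another deposited table holds, per the file headers, 1 log fold change per accession and a mark for up-regulated accessions. The submitters' processing notes name lumi, and its version is not given in the sources used here. From its values the series matrix is not log-transformed or centred. The shared lowest and highest values are what quantile normalization would leave, but the medians differ slightly and the method stays unknown.

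No probe annotation was used here. The authors' deposited fold changes were found to equal a difference of group means of a scaled inverse hyperbolic sine of the series matrix intensities, with 3 constants fitted to the data, so that probes could be joined to accessions by value within a tolerance of 1e-09. This joined 39314 of 39747 accessions, 33116 of them to 1 probe and 6198 to a group of 2 to 4 probes. The same search on values shifted by 1e-06 joined 18 accessions to 1 probe and 7 to a group. In all 46286 probes were joined. Accessions were named through the RefSeq gene table without their version numbers, which gave 27741 probes a current symbol, for 19166 symbols. The other probes stayed unnamed.

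The 2 deposited tables carry the groups crosswise. Each series matrix column correlated best with the array of the other group and the same number, with a Pearson r across probes between 0.99974 and 0.99997 against at most 0.997 for the next array. The join by value worked for 33131 probes with the series matrix groups crossed and for 21 with the groups as labelled. The main analysis had been fixed on the non-normalized table before the data were examined, and its column headings were kept.

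Intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the negative control signal inferred from the detection p-values, and log2-transformed. Probes with a detection p under 0.01 on at least 2 of the 4 arrays were kept, 19295 in all, of which 14915 had a current symbol. The probe with the highest mean stood for each of 11270 genes. Knockdown was compared with control with lmFit and eBayes with a trend, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Each siRNA was compared with the 2 controls, and with the other siRNA, in a fit with 3 groups, in which the spread comes from the 2 control arrays and a lone array is assumed to vary like them. For the agreement of the siRNAs, 100 sets of unchanged samples against shared controls were simulated from the fitted variance of each gene. A gene whose probe was not above background on either array of a group has only a bound there. It was computed from the brighter group's mean and, per array of the dim group, the higher of the probe's value and the lowest value among detected probes.

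The 28 gene lists were fixed before the data were examined and compared with all other genes by limma's camera with a preset correlation of 0.01, and beside it by camera with an estimated correlation and by fry, each adjusted over the lists. Lists with fewer than 5 measured members were described only. The genes named are TARBP2, DICER1, APP and ZNF395, then the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, leaving out LOC, orf and accession-only names, then the 3 members with the smallest p in each list described, and the 5 genes with the smallest p in each direction between the siRNAs. Any gene named outside this rule is said to be so. Some genes that the rule takes are not reported here.

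The tests were run on simulated data with the measured means and the fitted variances of the 11270 genes. The noise was normal and independent between genes, as the model assumes, so departures from the model were not tested. For knockdown against control, the limma fit recovered 36.0% of genes changed by 0.25 on the log2 scale, 88.0% of those changed by 0.5, and 100% of those changed by 1 or 2, and 4.14% of the calls were false. With no simulated effect it called 2 genes. Between the siRNAs, 68.0% of genes changed by 0.5 were recovered, and 0 genes were called in 1 simulation with no effect, in which all arrays vary alike. With no effect, camera called 0 of the lists, but the simulated genes vary independently, so calls for lists of correlated genes were not tested. A simulated shift of 0.2 in 1 list gave a camera adjusted p of 3.18e-67 with the preset correlation and 0.419 with an estimated correlation. The setting with an estimated correlation thus missed a shift of this size.

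Alternatives covered the background correction, the normalization, the deposited series matrix, the filter on dim probes, the probe per gene, the variance model, each array left out in turn, the replicate number as a block and, for lists, the set test. The series matrix with its columns matched to the arrays, and the classes of noncoding RNA, were added after the data were seen. Nothing in the labels names a chip, position or day of hybridisation. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.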

Results

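RNA of MDA-LM2 shDicer cells was profiled on 4 Illumina arrays, 2 of TARBP2 knockdown, labelled with separate siRNAs that the design text calls independent, and 2 of control siRNA transfection. TARBP2 encodes an RNA-binding protein that partners Dicer in small RNA processing and also binds structured elements in messenger RNA. The comparison asks which transcripts change when it is depleted in cells that also carry a hairpin against Dicer. Between 39.1% and 40.8% of the 47323 probes were detected on an array, and the median signal was 68.1 to 71.0. The number of arrays limits the precision. Nothing says that the samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

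TARBP2 was measured first. Its brightest probe, for NM_134323, read 6.11 with siTARBP2-1 and 5.79 with siTARBP2-2, against 9.27 and 9.25 in the controls, on the log2 scale. The knockdown mean was 5.95 ± 0.23 (SD, n = 2) and the control mean 9.26 ± 0.01 (SD, n = 2). This is a log2 fold change of -3.31 with a standard error of 0.11, or 9.89-fold lower (limma adjusted p = 2.09e-10). A second probe, for NM_134324, gave -2.89. In the authors' deposited table the values for these accessions are -1.91 and -1.29, on a scale that compresses low signals. In the series matrix as labelled, where the groups stand crosswise to the headings of the non-normalized table, the same change is 2.57.

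Depleting TARBP2 came with a change in many transcripts, most of them small. Of 11270 genes, 3851 (34.2%) passed the threshold, 1921 higher and 1930 lower in knockdown, with a median absolute log2 fold change of 0.34. At least 2-fold changes were found for 54 higher and 41 lower genes, and 4952 genes had an unadjusted p under 0.05. The groups did not overlap for 67.0% of genes, where chance gives 33.3%. The median over all genes was -0.0088. Scaled to a common median without quantile normalization, the arrays gave 1792 higher and 864 lower genes, so 67.5% of calls were higher against 49.9%. The smallest p that an exact permutation of 2 against 2 arrays can give is 0.333, so the calls rest on the variance model shared across genes.

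The largest rise was that of SH2D3A, an adaptor with an SH2 domain, with a log2 fold change of 2.40 and a standard error of 0.14 (limma adjusted p = 5.34e-08). The chemokine genes CCL3L3 and CCL3 followed with 2.07 and 1.95. Their sequences are nearly identical, so the probes may not tell them apart, and CCL3 was detected on 1 of the 2 control arrays. SAA4, a serum amyloid A gene with close paralogs, rose by 1.82, LTB, which encodes lymphotoxin beta, by 1.65, and FLG, which encodes filaggrin, by 1.63. LTB was also detected on only 1 control array. ODAPH and MPP4 were not above background in either control and were at least 2.31-fold and at least 2.44-fold higher in knockdown (limma adjusted p = 1.64e-05 and 6.78e-06). The 18S ribosomal RNA probe RNA18SN5 rose by 1.55. The small nuclear RNA probe RNU4-1 gave 1.52 with a standard error of 0.28, a call that ended with a robust variance model (limma adjusted p = 0.234) and without a variance trend (0.0521).

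After TARBP2, the largest fall was that of HSPA13, a microsomal member of the HSP70 family, at -1.98 with a standard error of 0.08 (limma adjusted p = 2.96e-09). A second bright probe of HSPA13 also gave -1.98. PTBP3, a polypyrimidine tract binding protein, fell by 1.86 on the log2 scale, with -1.89 on its other probe. ERLIN2, a protein of the endoplasmic reticulum membrane, gave -1.77, while its other probes, for NM_001003791, gave -0.43 and -0.18 near background. SGCB, which encodes beta-sarcoglycan, gave -1.48. SACM1L, a phosphoinositide phosphatase, gave -1.37, TMEM33 gave -1.36, PCDHB10 gave -1.35 and TAPT1 gave -1.34. ZNF395 and APP are transcripts named in published work on TARBP2. ZNF395 rose by 0.66 with a standard error of 0.07 (limma adjusted p = 1.46e-05). APP gave -0.02 with a standard error of 0.07 (adjusted p = 0.879). DICER1 gave -0.09 with a standard error of 0.08 (adjusted p = 0.441).

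**Figure D1:**
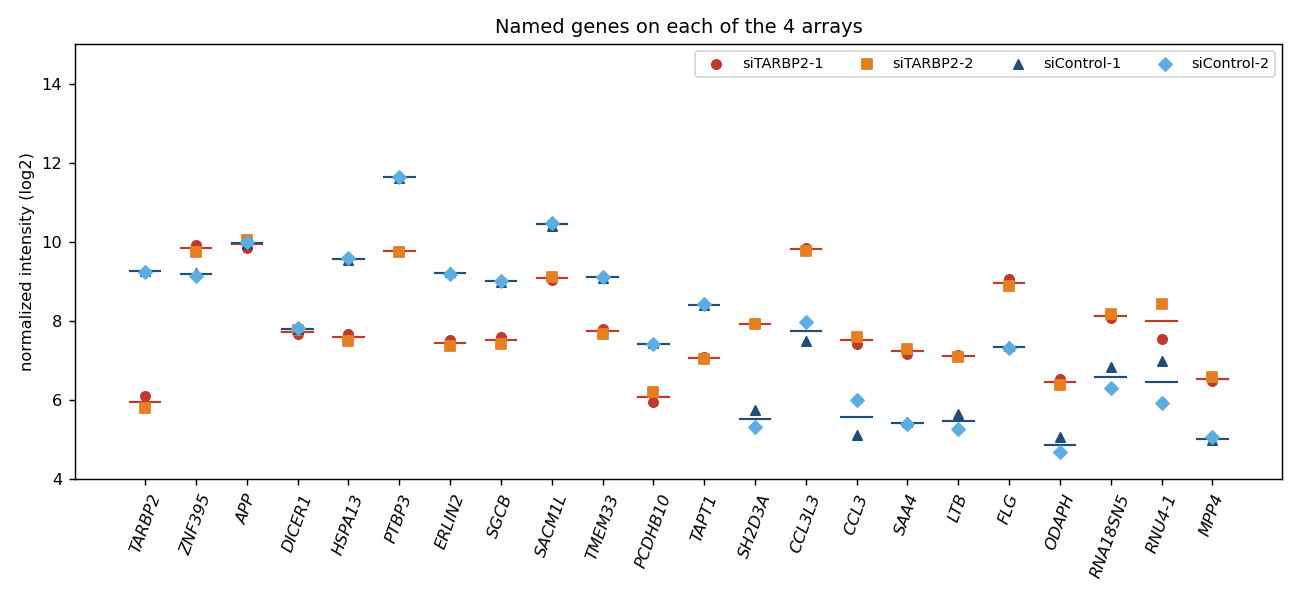
Normalized log2 intensity (vertical axis) of the named genes (horizontal axis) on each of the 4 arrays, with the mean of each group as a line. TARBP2 lies at 6.11 and 5.79 on the knockdown arrays and at 9.27 and 9.25 on the control arrays, while APP overlaps between the groups.

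Most measured epithelial markers rose. Of 22 listed members only 11 passed the detection filter and were measured. Of these 8 rose and 0 fell, or 9 and 0 when adjusted over the list alone, with a mean log2 fold change of 0.57 (camera adjusted p = 2.04e-06). The list was not called with an estimated correlation (camera adjusted p = 0.569), and its mean was 0.31 with no detection filter. All 7 lists called with the preset correlation share this adjusted value. Before adjustment, camera with an estimated correlation gave p = 0.0300 for epithelial markers, 0.0512 for the endoplasmic reticulum, 0.0656 for hypoxia and 0.0982 for mitosis. For the mesenchymal, interferon and cholesterol lists it gave 0.146, 0.148 and 0.169. The setting with an estimated correlation missed a simulated shift of 0.2 too, in another list and with genes that vary independently. A call lost there, for this list or those below, does not by itself show the absence of a shift. The simulation does not tell why any of these calls was lost. KRT19 rose by 1.04, KRT7 by 0.76 and KRT8 by 0.70, all keratins of simple epithelia. KRT18, the usual partner of KRT8, gave -0.01, and is named after its value was seen. Mesenchymal markers and matrix genes also shifted upward as a list, with 13 of 28 higher and 6 lower, or 13 and 7 adjusted over the list alone (mean 0.23, camera adjusted p = 0.0309). This call too was lost with an estimated correlation (adjusted p = 0.569). The collagen genes COL4A1, COL1A1 and COL8A1 rose by 1.09, 1.00 and 1.24. The call of the mesenchymal list ended without siTARBP2-2 (camera adjusted p = 0.0657) and without a variance trend (0.0742).

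Genes of double-stranded RNA sensing and the type I interferon response shifted upward. Of 35 measured members 20 rose and 2 fell, the same counts when adjusted over the list alone (mean 0.25, camera adjusted p = 2.04e-04). The call was lost with an estimated correlation (camera adjusted p = 0.569). It was also lost by fry, which asks whether members move on balance in 1 direction (adjusted p = 0.0563). The correlation estimated among its members was 0.110, above the preset 0.01, so the call rests on a preset that is low for this list. OAS2, which makes the activator of RNase L, rose by 0.86, and the interferon-induced IFIT3 and IFIT2 rose by 0.68 and 0.53. Among the members that fell was TLR3 at -0.32, a sensor of double-stranded RNA, named after its value was seen.

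Chaperones and unfolded protein response genes of the endoplasmic reticulum shifted downward. Of 17 measured members 0 rose and 10 fell, or 1 and 11 adjusted over the list alone (mean -0.24, camera adjusted p = 7.19e-04). With an estimated correlation the list was not called (adjusted p = 0.569). ATF6, a sensor of the unfolded protein response, gave -0.46, and MANF and DNAJB9, both induced by it, gave -0.35 and -0.31. The call of DNAJB9 ended with median scaling (limma adjusted p = 0.0753). HSPA5, the main chaperone of that compartment, gave -0.01 and is named after its value was seen.

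Hypoxia and glycolysis genes shifted upward, with 10 of 32 higher and 2 lower, the same counts adjusted over the list alone (mean 0.12, camera adjusted p = 0.00800, and adjusted p = 0.569 with an estimated correlation). The glucose transporters SLC2A1 and SLC2A3 rose by 0.53 and 0.39 and the hexokinase HK1 by 0.35. Cholesterol and fatty acid synthesis genes had 9 of 29 higher and 1 lower, the same counts adjusted over the list alone (mean 0.09, camera adjusted p = 0.0371, and adjusted p = 0.569 with an estimated correlation). SCD, the stearoyl-CoA desaturase, rose by 0.45 and ACLY, the ATP citrate lyase, by 0.32, while the desaturase FADS1 gave -0.48. Genes of G2/M and mitosis shifted downward, with 3 of 31 higher and 12 lower, the same counts adjusted over the list alone (mean -0.11, camera adjusted p = 0.0371, and adjusted p = 0.569 with an estimated correlation). HMMR, TTK and CENPE, which act at the spindle or kinetochore, gave -0.56, -0.50 and -0.44. Without a variance trend the cholesterol and mitosis lists had 0.0742 and 0.0893, and with the mean of probes the cholesterol list had 0.105. With median scaling the adjusted p of all 3 were 0.166, 0.227 and 0.101, in the order given, and the means of the cholesterol and mitosis lists were 0.14 and -0.07. Without siTARBP2-2 the cholesterol and mitosis lists had 0.0801 and 0.0657, without siControl-2 they had 0.0730 and 0.0617, and without siControl-1 the cholesterol list had 0.0563.

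**Figure D2:**
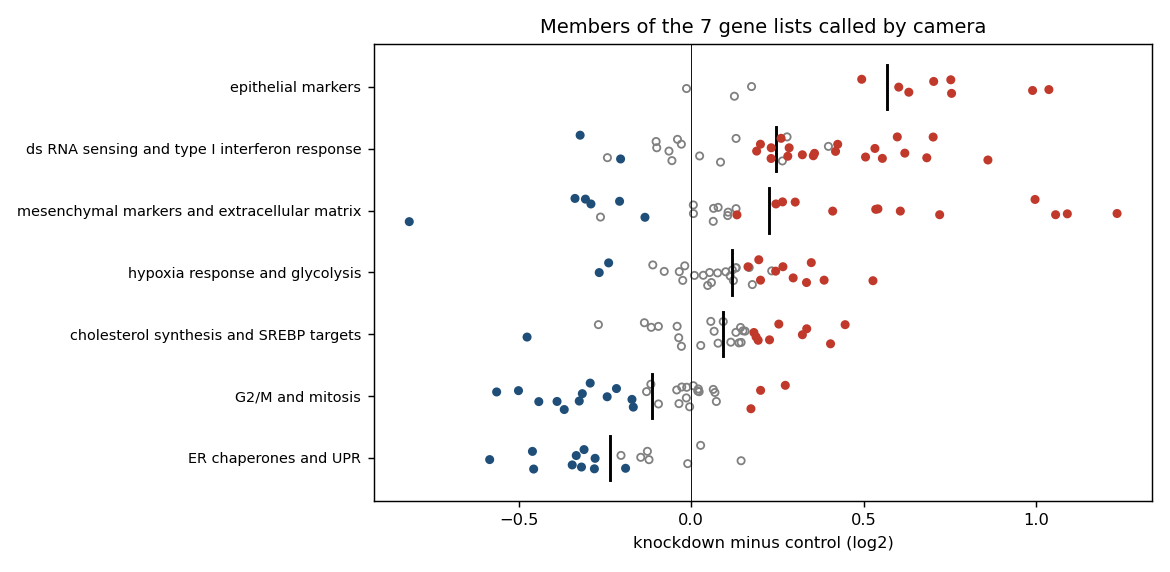
Log2 fold change, knockdown minus control (horizontal axis), of each member of the 7 gene lists called by camera. Filled points passed an adjusted p of 0.05 over all genes (red higher, blue lower), open points did not, and the black line is the list's mean, from 0.57 for epithelial markers to -0.24 for endoplasmic reticulum chaperones.

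The other lists were not called by camera. In the RNA interference machinery 2 of 18 genes rose and 6 fell, the same counts adjusted over the list alone (camera adjusted p = 0.212). TSNAX, a subunit of the passenger-strand nuclease C3PO, gave -0.45, RAN, the transport GTPase, gave -0.21 and the RNA editing enzyme ADAR rose by 0.26. The call of RAN ended with median scaling (limma adjusted p = 0.131), with the mean of its probes (0.235) and without a variance trend (0.0608). Among ATF4 targets 6 of 28 rose and 9 fell, or 8 and 9 adjusted over the list alone (camera adjusted p = 0.758), and their median of 0.0046 and mean of -0.05 differ in sign. DDIT3, a transcription factor of this response, gave -0.75, WARS1 gave -0.51 and SLC7A5 rose by 0.34. NF-kB and cytokine genes moved both ways, 8 of 25 higher and 7 lower, or 9 and 8 adjusted over the list alone (camera adjusted p = 0.841). IL6 and CCL20 rose by 0.61 and 0.93, and IL11 gave -0.89. Among p53 targets 2 of 19 rose and 3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.748), with TP53INP1 at -1.11, CCNG1 at -0.33 and GDF15 at -0.44. Of 21 genes tied to lung metastasis of MDA-MB-231 cells 6 rose and 4 fell, the same counts adjusted over the list alone (camera adjusted p = 0.951). SPARC rose by 0.72, and ID3 and ID1 gave -0.67 and -0.55. Of markers of blood cells 0 of 5 measured passed (camera adjusted p = 0.503), 0 also adjusted over the list alone, and 2 had an unadjusted p under 0.05. Of these markers CD14 gave 0.21 (limma adjusted p = 0.0697) and passed with median scaling, at 0.28 (adjusted p = 0.0444). Of endothelial and fibroblast markers 3 of 5 rose, the same adjusted over the list alone, COL1A1 by 1.00, LUM by 0.44 and ACTA2 by 0.26 (camera adjusted p = 0.145). COL1A1 also belongs to the matrix list, and the calls of LUM and ACTA2 ended without detection filtering (limma adjusted p = 0.101 and 0.128) and when single arrays were left out, siTARBP2-2, siControl-1 or siControl-2 for LUM (limma adjusted p = 0.221, 0.0951 and 0.0613) and any of the 4 for ACTA2 (0.0949 to 0.134).

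The arrays of both siRNAs differed from the control arrays in similar ways. With siTARBP2-1 2798 genes changed, 1410 higher and 1388 lower, and with siTARBP2-2 3067 changed, 1536 higher and 1531 lower. Past the threshold with both siRNAs were 1111 genes higher with each and 1037 lower with each. Independent lists would share 192 and 189, and simulated unchanged samples against shared controls shared at most 1 gene in either direction over 100 sets. Over all genes 82.1% had the same sign with both siRNAs, against 60.8% in simulated unchanged samples. Across genes, which are not independent replicates, the fold changes of both siRNAs correlated with a Pearson r of 0.876 and a Spearman rho of 0.830. The same controls enter both, and simulated unchanged samples gave an r of 0.335. The covariance was 0.0810 against 0.00508 in the simulation. Part of the excess in shared calls may come from the shared controls, which are too few to split into pairs. The simulated shared calls cannot show how large that part is, since with no effect hardly any gene passes with both siRNAs. Among genes with an unadjusted p under 0.05 with both siRNAs, 95.9% had the same sign in the simulation and 99.8% in the data. Shared controls alone thus gave the same sign for most such genes. With a different control array for each siRNA, r was 0.761 with the controls of the same number and 0.758 with the controls exchanged. The counts for single siRNAs depend on the variance model, with 602 and 797 genes without a trend, and on the scaling, with 1182 and 1548 after median scaling. For siTARBP2-2 it was 2039 with no detection filter.

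**Figure D3:**
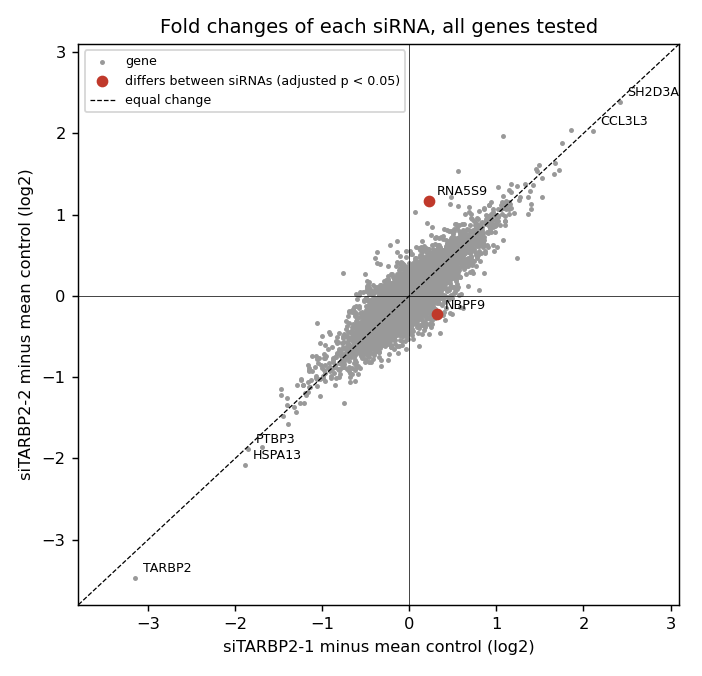
Log2 fold change of each of the 11270 genes with siTARBP2-1 (horizontal axis) and siTARBP2-2 (vertical axis), each against the mean of the 2 controls. Points lie along the dashed line of equal change (r = 0.876), and the 2 genes that differed between the siRNAs, RNA5S9 and NBPF9, are in red.

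Compared directly, 2 genes passed the threshold between the siRNAs, and 654 had an unadjusted p under 0.05. Each side is a single array and the spread comes from the control arrays, so these calls rest on the assumption that all arrays vary alike. NBPF9, of a multicopy family, was 0.55 higher with siTARBP2-1 on the log2 scale (standard error 0.07, limma adjusted p = 0.0472). The 5S ribosomal RNA probe RNA5S9 differed by -0.94 (standard error 0.12, limma adjusted p = 0.0472). Other genes in either direction did not pass. Higher with siTARBP2-1 were PIGV by 0.56, RPPH1 by 0.46, NBPF10 by 0.34 and ATP5MC1 by 0.33, and lower were RNU4-2 by -0.98, CIP2A by -0.78 and CD2AP by -0.49. The count was 11 with median scaling, 4 with cyclic loess, 5 probes over all probes and 0 with no detection filter, with detection on all 4 arrays, with the mean of probes or without a variance trend.

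The authors' deposited table marks 1240 accessions as up-regulated, each with a deposited log fold change of at least 0.230. Of 961 marked genes that were tested, 950 were called higher and 0 lower. Another 971 genes were called higher and are not marked, with a median log2 fold change of 0.27. Across genes the deposited and the refitted fold changes correlated with a Pearson r of 0.901. Both come from the same arrays, and probes were joined to accessions by the deposited values. The agreement thus partly follows from the join and is no separate support.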

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

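All tests of explanations in this part were chosen after the results they bear on had been seen.

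Between the siRNAs, NBPF9 (0.55 higher with siTARBP2-1, log2) and RNA5S9 (-0.94) passed the threshold. Each side is 1 array, the spread is that of the controls, and the count was 0 with no detection filter, with detection on all 4 arrays, with the mean of probes and without a trend. NBPF9 gave 0.32 with siTARBP2-1 alone and -0.22 with siTARBP2-2 alone, each against the controls. RNA5S9 gave 0.23 and 1.17. Both probes belong to multicopy families. In data outside the comparisons of named genes, 932 probes without a current symbol changed in knockdown, 473 higher and 459 lower (limma on all probes, adjusted). The largest rises were 2.22 for XM_926554 and 2.13 for XM_001127070, and the largest falls were -1.45 for AL833463 and -1.31 for BG434785. In the series matrix as labelled, TARBP2 was 2.57 higher in the samples named knockdown.

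The first pattern is that the arrays of both siRNAs showed nearly the same changes. The shared controls are argued against as the whole cause, since with a different control array for each siRNA the correlation across genes was still at least 0.758. Whether both knockdown arrays carry the same material, or separate siRNAs as the design text says, cannot be told apart from these values. The SD over genes between the knockdown arrays was 0.964 times that between the control arrays, a value that either reading allows. Handling that differed between the groups (no chip or day is given), off-target effects shared by the siRNAs (whose sequences are unknown here) and the loss of TARBP2 itself all stay open and untested.

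The second pattern is the crossed groups. Crossed headings in the non-normalized table are argued against, since TARBP2 was lower on the arrays headed siTARBP2, at -3.31, on the assumption that the siRNAs lowered their target. The value of 2.57 in the series matrix follows from the same arrays standing crosswise there, so it is no separate support for crossed columns in that table. On the assumption that the siRNAs lowered their target, the series matrix columns are the crossed ones, since the groups are exchanged between the tables. The deposited fold changes joined 33131 probes with the series matrix groups crossed, and 21 with the groups as labelled. No biological explanation was tested for this pattern.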

How the results depend on the processing

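The series matrix with its columns matched to the arrays and the RNA classes were alternatives and results chosen after the data were seen. In every alternative but 1 TARBP2 was lower in knockdown, from -3.47 to -2.57 over 16 alternatives. In the series matrix as labelled it was 2.57 higher, since the groups stand crosswise there. The count of changed genes lay between 2614 and 3914 over the alternatives that count genes, and 5404 of 19295 probes changed when all were tested. Of lower genes there were 864 with median scaling and 1263 to 1558 with 1 array left out. For single siRNAs 1182 and 1548 genes changed with median scaling and 602 and 797 without a trend, and for siTARBP2-2 it was 2039 with no detection filter. The genes that differed between the siRNAs were 11 with median scaling, 4 with cyclic loess, 7 in the series matrix as labelled, 5 probes over all probes, and 0 with no filter, with detection on all 4 arrays, with the mean of probes and without a trend. The correlation between the siRNAs was 0.896 without background correction, 0.894 with an offset of 50, 0.897 in the matched series matrix, 0.898 in it as labelled, 0.796 with no filter, 0.887 with detection on all 4 arrays, 0.848 over all probes, and 0.761 and 0.758 with separate controls. Lists called were 4 with median scaling, 4 without a trend, 0 with an estimated correlation and 4 to 7 with 1 array left out. The epithelial, interferon and endoplasmic reticulum lists were called by camera with the preset correlation in 15 of 15 alternatives, though not with an estimated one. The robust setting does not enter camera and gave no list value. The replicate number as a block gave 3869 genes, and the numbers do not pair the samples, with a correlation of same-numbered deviations of 0.0051. Arrays were left out after normalization and filtering, and a lone array was assumed to vary like the other group. Signal near background limits the dim probes.

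These values, none past the threshold in the main setting, changed sign, and the cause was not tested. The mean of immediate early genes was 0.011 without background correction, 0.0074 with an offset of 50, 0.033 with median scaling, 0.018 in the matched series matrix and 0.014 over all probes. That of ribosomal proteins was -0.0015 without background correction, -0.0011 with an offset of 50, -0.0031 with cyclic loess and -0.0019 in the matched series matrix. Lysosome genes gave 0.036 with median scaling and 0.0033 with loess. Lung metastasis genes gave -0.00081 with no filter and -0.029 over all probes. Apoptosis regulators gave -0.0054 with detection on all 4 arrays and -0.025 over all probes. Heat shock genes gave 0.0043 with the mean of probes. With median scaling APP gave 0.035, NBPF10 0.0027 and RPPH1 0.023, and with the mean of probes APP gave 0.015 and CD68 -0.0020. With 1 array left out in turn, the list means ranged over -0.028 to 0.0023 for immediate early genes, -0.0071 to 0.0080 for ribosomal proteins, -0.026 to 0.014 for lysosome genes and -0.012 to 0.036 for apoptosis regulators. The fold changes ranged over -0.12 to 0.083 for APP, -0.033 to 0.17 for CD68, -0.22 to 0.32 for NBPF9, -0.20 to 0.14 for NBPF10, -0.27 to 0.20 for RPPH1, -0.27 to 0.063 for ATP5MC1 and -0.51 to 0.27 for CIP2A. NBPF9, NBPF10, RPPH1, ATP5MC1 and CIP2A were named for their difference between the siRNAs. Their change of sign when a knockdown array is left out partly follows from that choice.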

Other observations

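Noncoding RNA probes were grouped by class. This grouping and the tests of explanations for it were chosen after the data were seen, while the gene lists in this part were fixed beforehand. The 3 ribosomal RNA probes were all called higher in knockdown, with a median log2 fold change of 0.85, which was 1.49 with the mean of probes and 0.65 to 1.24 with 1 array left out. Of 9 small nuclear RNA probes all 9 were positive and 5 were called higher, with a median of 0.38. RNU6-1, the U6 RNA of the spliceosome, rose by 0.98 (standard error 0.06, limma adjusted p = 1.25e-07) and differed little between arrays of a group. Of 92 small nucleolar RNA probes 18 were lower, 4 higher and 20 positive, with a median of -0.17, where of 10923 protein-coding genes 1883 were lower, 1880 higher and 5315 positive. No class was tested as a set. The direction of these 3 medians was the same under each scaling tried, from 0.81 to 0.92, 0.29 to 0.44 and -0.17 to -0.10. The call of RNA5S9, 1 of the ribosomal RNA probes, ended with a robust variance model (limma adjusted p = 0.360), without a trend (0.137), without a detection filter (0.0815), without siTARBP2-2 (0.148) and without siControl-2 (0.0554). RNU4-1 and RNU4-2 lost theirs with a robust model (0.234 and 0.242) and without a trend (0.0521 and 0.0681). The probes of 4 Y RNAs, 25 microRNA genes and 81 long noncoding RNAs had medians of -0.06, -0.0025 and -0.02. These families have near-identical copies, and the single probes are uncertain.

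The positive values of the 12 ribosomal and small nuclear RNA probes, 4 of which did not pass the threshold, may be technical, since the labelling starts from total RNA and these RNAs mostly lack a poly(A) tail. More short or unpolyadenylated RNA of every kind in the knockdown samples is argued against by the small nucleolar RNA probes with a mean log2 level of 7 or more, 28 in all. Their median was -0.23 with an SD of 0.25, below the median of 0.67 of the 12 probes by more than that SD. This leaves open a technical cause that acts on ribosomal and small nuclear RNA alone, which was not tested. Variation between arrays of a group stays open too. Over the 12 probes the larger difference within a group was 0.803 times the difference between groups at the median, and it was as large or larger for 4 of them. An effect of TARBP2 loss on these RNAs is a hypothesis that these arrays leave untested.

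Other lists fixed beforehand were not called by camera. Adjusted over the list alone, the counts given here were the same except where stated. TGF-beta and SMAD targets had 5 of 17 higher and 7 lower (adjusted p = 0.836), with TGFBI up by 0.41 and ID3 and ID1 at -0.67 and -0.55. NRF2 targets had 2 of 20 higher and 7 lower (adjusted p = 0.145). HMOX1, the heme oxygenase, rose by 0.72, while AKR1C3 and TXNRD1 gave -0.62 and -0.52. Immediate early genes had 7 of 22 higher and 4 lower, or 8 and 4 adjusted over the list alone (adjusted p = 0.779), with EGR1 at -1.16, DUSP5 up by 0.65 and MYC by 0.34. Their mean of -0.013 is against camera's upward direction. YAP and TEAD targets had 5 of 15 higher and 2 lower, or 5 and 3 adjusted over the list alone (adjusted p = 0.182), with TGFB2, WWC1 and AJUBA up by 0.62, 0.48 and 0.46. The call of AJUBA ended with the mean of its probes (limma adjusted p = 0.164). mRNA decay factors had 11 of 34 higher and 5 lower (adjusted p = 0.758), with SMG1 at -0.58, ZFP36L1 up by 0.46 and PAN3 at -0.35. Apoptosis regulators had 4 of 20 higher and 5 lower, or 5 and 6 adjusted over the list alone (adjusted p = 0.962), with BAK1 and BID up by 0.46 and 0.39. Their median of -0.0065 and mean of 0.012 differ in sign. Oxidative phosphorylation genes had 1 of 41 higher and 10 lower, or 1 and 7 adjusted over the list alone (adjusted p = 0.145). Replication-dependent histones had 0 of 11 higher and 3 lower with a mean of -0.16 (adjusted p = 0.118, from 0.0254 with no detection filter, which called the list, to 0.240 over the alternatives), and cytosolic ribosomal proteins 7 of 47 higher and 5 lower, or 7 and 3 adjusted over the list alone (adjusted p = 0.882), with a negative median of -0.02 against a mean of 0.00043. G1/S genes had 2 of 30 higher and 2 lower, or 1 and 2 adjusted over the list alone (adjusted p = 0.804), the heat shock response 2 of 14 and 2 (adjusted p = 0.727), lysosome and autophagy genes 4 of 26 and 3, or 2 and 0 adjusted over the list alone (adjusted p = 0.882) and housekeeping genes 1 of 15 and 2, or 1 and 1 adjusted over the list alone (adjusted p = 0.727). By fry, which does not compare a list with other genes, the ATF4, TGF-beta, NRF2 and housekeeping lists passed as well, and the interferon list did not.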
